A study of Mus musculus with 4 samples.

How the data were processed

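The data were RNA-seq measurements of mouse T cells. Naive CD4+ T cells, sorted as CD62L+CD44-CD25- per the labels, came from the spleen and lymph nodes of wild-type C57BL/6 mice and of Fas-deficient mice that the design text calls lpr and the labels call Fas-/-. The cells were activated for 48 h on plate-bound anti-CD3 and anti-CD28 antibodies, either with no cytokine (Th0) or with TGF-β1 and IL-6 (Th17). Per the labels' protocols, total RNA was treated with DNase, selected for poly(A) tails in 2 rounds on oligo-dT beads, fragmented with zinc and made into libraries by ligating an RNA adapter, reverse transcription and PCR.

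Per the submitters' processing notes, TopHat2 2.0.10 and Cuffdiff 2.1.1 were used, with the mouse build mm9. The gene annotation, read filters, use of strand, sequencing depth and any pooling of replicates are not given in the sources used here. The authors deposited 2 comparison tables, Fas-deficient against wild-type in Th0 and in Th17, each with 23292 gene rows. Per the file headers, each row holds the locus, a value for each genotype, a log2 fold change, a test statistic, a p-value, a q-value and a flag of significance. The values are FPKM (fragments scaled to transcript length and to the mapped total), normalized by the authors before deposit, and their fold changes are deposited on the log2 scale. The test statistic was read as a score given by the authors and was not used. The deposited p-values and q-values come from the authors' test, whose replicate number and dispersion setting are not given in the sources used here. The FPKM of Fas-deficient over wild-type gave back the deposited log2 fold changes within 3.892e-05.

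Each of the 4 samples was placed in its group by its title, and each group held 1 sample. No test of a difference between samples was made here, and no error between replicates can be given. A fit of genotype with condition as a block, which leaves 1 residual degree of freedom and takes the difference between the conditions as error, was not run. For each gene the log2 ratio of Fas-deficient over wild-type was computed as log2 of (FPKM + 1), with a pseudocount of 1, which understates the change of low genes. A gene counted as expressed in a condition when either value was at least 1 FPKM. Differences over the whole table were described by a rule of at least 2-fold, and those in gene lists by a rule of at least 1.5-fold. The authors' calls were counted at their own flag, a q-value of at most 0.05, in each direction. The words rose and fell are kept below for genes with this flag in the authors' deposited table, and other genes are given as values.

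For each of 28 gene lists, the median log2 ratio of the expressed members was computed, with its percentile among 10000 random lists of the same size drawn within 20 bins of mean log2 expression (seed 11). A percentile describes these samples and is not a test. Beside the authors' calls over all genes, their deposited p-values were adjusted by the Benjamini-Hochberg method over the list alone at 0.05. Symbols were matched directly, or through synonyms of the RefSeq gene table. No symbol of the mitochondrially encoded list was matched, Ighm and Ighd of the B cell list and Hbb-bt of the red cell list stayed unmatched, and every other listed symbol was matched, where synonyms and symbols that the tables join in 1 row counted once. The neighbours of Fas were the 192 genes that start within 10 Mb of it. Gene symbols and loci were taken as the tables give them, with 1 added to each start, since the end minus the start equalled the RefSeq span for 35.3% of genes and that difference plus 1 for 2.23%.

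The lists, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Fas first, then Stat1, Stat3, Rorc, Il17a, Il17f, Il23r, Il21, Tbx21, Ifng, Foxp3 and Il2. It added, per condition, the 12 called genes with the largest positive and the 12 with the largest negative log2 ratio among genes of at least 5 FPKM in either sample, filled to 6 with uncalled genes where fewer than 6 were called. It also added up to 4 members of each list with the largest absolute log2 ratio. Predicted genes without a common name, pseudogenes, receptor segments, snoRNAs and microRNAs were counted and not named. Genes named outside this rule are either further called genes or list members, or serve to check the labels or a marker, or stand as values among the other observations, and were chosen after their values were seen.

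The tables are scaled within themselves, so ratios were computed within a table, and levels set across the tables carry that limit. The 4 rows whose joined symbols differ between the tables were left out of comparisons across conditions. The alternatives were pseudocounts of 0.1 and 5, no filter or a filter of 5 FPKM, centring on the median of expressed genes, scaling to a common upper quartile, tested rows alone, the mean in place of the median of a list, stricter calls, and the deposited log2 fold change.

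The size rule and the percentile of a list were tested on simulated data. In the simulated Th0 comparison over 10785 genes, 200 genes changed 2-fold were put past the 2-fold line in 49.5% of cases, and those changed 3-fold in 99%. In the simulated Th17 comparison over 10796 genes the shares were 48.5% and 98.5%. The changed genes were drawn from well expressed genes alone, and a 2-fold change lies on the line itself. Unchanged lists of 25 genes fell outside the central 95% of random lists in 6.5% of cases in Th0 and 5.5% in Th17, and lists shifted by 0.2 lay above it in 100% of cases in each. Simulated genes varied independently, while members of a real list can vary together and some real lists are smaller. These shares may therefore not hold for the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.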

Results

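Messenger RNA was measured in T helper cells that carry or lack a working Fas gene. Fas is a death receptor of the TNF receptor family, and lpr mice, which lack normal Fas, accumulate T cells and develop autoimmunity. The series asks, by its title, how Fas affects the differentiation of Th17 and Th1 cells and the transcription factor STAT1. There were 4 samples, 1 per group, namely wild-type Th0, Fas-deficient Th0, wild-type Th17 and Fas-deficient Th17, each taken at 48 h. Only FPKM values were used, so the depth of each sample is unknown. The values summed to 764393 and 719453 FPKM in wild-type and Fas-deficient Th0 and to 763895 and 768314 FPKM in wild-type and Fas-deficient Th17. Between 10521 and 10609 genes reached 1 FPKM in each sample. The differences below have no replicate check.

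The targeted gene was measured first. Fas, on chromosome 19 from 34365149 to 34402260 (mm9), fell from 33.1 FPKM in wild-type Th0 cells to 17.7 in Fas-deficient Th0 cells, with q = 0.0273 in the authors' deposited table. In Th17 cells it stood at 11.5 FPKM in the wild type and 7.03 in the Fas-deficient sample, and the authors' deposited table did not call it (q = 0.998). The log2 ratios were -0.87 and -0.64. Transcripts of Fas were therefore lower and still present in both Fas-deficient samples.

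The culture conditions were visible in the wild-type samples, whose levels come from separate tables that may be normalized separately. Il17a, the gene of the signature Th17 cytokine, stood at 6.83 FPKM in Th0 and 1059.7 in Th17. Il17f stood at 19.04 and 2218 FPKM, Il21 at 1.26 and 92.6, and Rorc, which encodes the Th17 master regulator RORγt, at 6.04 and 46.8. Il23r, the receptor subunit through which IL-23 sustains Th17 cells, stood at 0.135 and 3.19 FPKM. The Th1 regulator Tbx21 (T-bet) went the other way, with 28.7 FPKM in Th0 and 2.92 in Th17, as did Ifng with 5.91 and 0.395, Gata3 with 31.1 and 2.86 and Il2 with 1063 and 534.5. Foxp3, the regulator of regulatory T cells, stood at 3.35 and 12.6 FPKM. Actb differed less, at 2254 and 2850.4 FPKM, and Cd4 stood at 175.6 and 96.9.

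**Figure D1:**
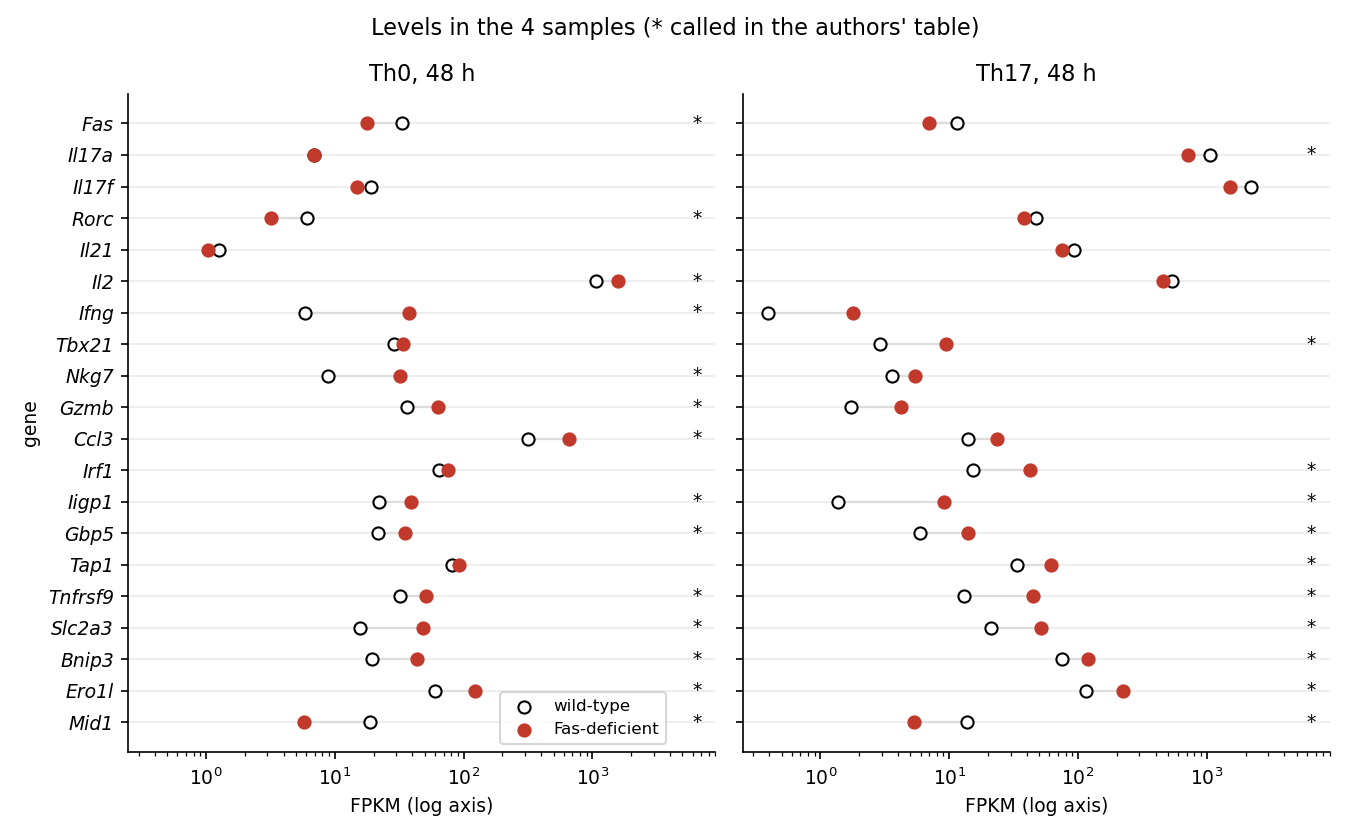
FPKM on a log axis of 20 genes in wild-type (open circles) and Fas-deficient (filled circles) samples, in Th0 cells on the left and Th17 cells on the right, with 1 sample per circle and an asterisk where the authors' deposited table called the gene. Ifng rose from 5.91 to 37.6 FPKM in Th0, and Iigp1 from 1.37 to 9.13 FPKM in Th17.

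In Fas-deficient Th0 cells, the lists of Th1 genes, of glycolysis and hypoxia and of amino acid stress had medians above those of random lists, and part of their members rose. Ifng, which encodes interferon-γ, rose from 5.91 FPKM in the wild type to 37.6 in the Fas-deficient sample, a log2 ratio of 2.48. Slc2a3, a glucose transporter, rose from 15.7 to 48.1 FPKM. Il13, a type 2 cytokine gene, fell from 12.04 to 3.70 FPKM, and Rorc fell from 6.04 to 3.20. The authors' deposited table called 97 of 9265 tested genes, 74 higher and 23 lower in the Fas-deficient sample.

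The Th1 list had 19 expressed members and a median log2 ratio of 0.22, at percentile 100 of 10000 random lists. Of its 17 members tested in the authors' deposited table, 7 rose over all genes tested and none fell, against 9 higher and 2 lower adjusted over the list alone. Besides Ifng, Nkg7, a cytotoxic granule protein, rose from 8.92 to 32.2 FPKM. The chemokine genes Ccl3 and Ccl4 rose from 317.6 to 655.8 FPKM and from 309 to 483 FPKM, and Gzmb (granzyme B) from 36.2 to 63.0. Il12rb2, which completes the IL-12 receptor, rose from 13.9 to 21.02 FPKM and Tnf from 63.8 to 94.2. Xcl1 stood at 3.53 and 10.5 FPKM without a call. Some other members went the other way. Ccl5 was at 7.92 FPKM in the wild type and 3.13 in the Fas-deficient sample and Stat4 at 85.3 and 64.3, both uncalled. Tbx21 was higher and uncalled, at 28.7 and 33.6.

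Genes induced by interferon through STAT1 were higher in the Fas-deficient Th0 sample by a smaller amount. Of 48 expressed members 38 were higher, the median log2 ratio was 0.18, at percentile 100 of random lists, and 3 members were at least 1.5-fold higher and 2 at least 1.5-fold lower. The median was smaller with no filter on FPKM. The authors' deposited table called 6 higher and none lower, and 9 were higher and none lower adjusted over the list alone. Ly6a (Sca-1) rose from 66.9 to 132.2 FPKM, the interferon-inducible GTPases Iigp1 and Gbp5 from 22.0 to 38.9 and from 21.5 to 35.2, Gbp2 from 111.1 to 158.8 and Igtp from 135.2 to 184.9. Stat1 itself, on chromosome 1 from 52176282 to 52218709, stood at 105.7 and 125.9 FPKM, with q = 0.833 in the authors' deposited table. Among targets of type I interferon, Isg15 and Ifit1 were lower and uncalled, at 5.13 and 2.93 FPKM and at 1.83 and 0.769 FPKM, Ifih1 stood at 16.7 and 17.03, and Usp18 and Zbp1 were higher and uncalled, at 2.18 and 3.35 and at 10.3 and 13.1. Members of the Gbp family share sequence, so reads could be split between them.

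Of 27 genes of glycolysis and hypoxia, 25 were higher in the Fas-deficient Th0 sample, with a median log2 ratio of 0.22 at percentile 100. The authors' deposited table called 8 of them, all higher, and 11 were higher adjusted over the list alone. Besides Slc2a3 these included Bnip3, a mitophagy receptor induced by low oxygen, which rose from 19.6 to 43.6 FPKM, the aldolase gene Aldoc from 2.45 to 6.43, the oxygen sensor Egln3 from 12.2 to 26.5, Ero1l from 60.1 to 122.6, Ndrg1 from 11.9 to 23.8 and Vegfa from 10.2 to 16.5. The abundant enzymes moved less, with Ldha at 1339 and 1453 FPKM, Aldoa at 587.6 and 679 and Pkm at 785.8 and 909. Of 21 genes of amino acid starvation and ER stress, 20 were higher, with a median of 0.23 at percentile 100. The authors' deposited table called 4 higher and none lower, and 5 were higher and none lower adjusted over the list alone. The stress genes Trib3 and Atf3 rose from 7.40 to 14.9 FPKM and from 5.38 to 10.6, and Ddit4 and Sesn2, inhibitors of mTORC1 signalling, from 48.1 to 85.6 and from 10.1 to 16.2. The ER chaperone Hspa5 stood at 268.9 and 282 FPKM.

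Further genes rose in Fas-deficient Th0 cells. The metallothioneins Mt1 and Mt2, near-identical metal-binding proteins whose reads could be shared, rose from 31.3 to 79.7 FPKM and from 11.1 to 28.3. The chemokine receptor gene Cxcr4 rose from 2.22 to 8.21 FPKM, Slamf7, a receptor of cytotoxic lymphocytes, from 4.85 to 14.4, Serpine1 from 2.81 to 9.38, Mgarp from 3.51 to 9.22 and the MHC class II gene H2-Ab1 from 3.78 to 10.97. Antigen-presenting cells express H2-Ab1, and the 3 expressed B cell markers were higher in the same sample, with a median of 0.36. None of these 3 was tested in the authors' deposited table. The B cell genes Cd19 and Ms4a1 stood at 0.225 and 0.593 FPKM and at 0.325 and 0.684. A difference in the share of B cells was not tested. Il2, the T cell growth factor gene on chromosome 3 from 37019642 to 37024876, rose from 1063 to 1584 FPKM.

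Of the genes that fell in Fas-deficient Th0 cells, Mid1 went from 18.8 to 5.81 FPKM, a log2 ratio of -1.54. The small nuclear RNA gene Rnu12 was listed at 20.3 FPKM in the wild type and at 0 in the Fas-deficient sample and was also called. Penk, which encodes enkephalins, fell from 45.4 to 22.95 FPKM, Fam46a from 23.04 to 10.5, Bmyc from 61.5 to 34.5, Idi2 from 21.5 to 11.9, Cyr61 from 12.8 to 6.75 and Fcrl1 from 10.7 to 6.26. The Th2 list had a median of -0.21 over 8 expressed members, at percentile 0.01, and 7 of them were lower, while the median with no filter on FPKM was -0.083. The authors' deposited table called 2 of its members lower and none higher, Il13 and the chemokine receptor Ccr4, the latter from 51.5 to 37.1 FPKM, and 4 were lower and none higher adjusted over the list alone. Gata3, the Th2 regulator, stood at 31.1 and 25.2 FPKM and Ccr8 at 54.4 and 39.5, both uncalled. The list of naive and quiescent T cells had a median of -0.08 at percentile 0.7, with Satb1 falling from 106.4 to 68.4 FPKM and Ccr7 from 287 to 204 and no member rising. Adjusted over the list alone, 3 were lower and 2 higher.

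The Th17 list stood near 0 in Th0 cells, with a median of -0.04 over 20 members at percentile 13.6. Rorc was its 1 called member over all genes, and 2 were lower and none higher adjusted over the list alone. Il17a stood at 6.83 and 6.95 FPKM, Il17f at 19.04 and 14.9, Il21 at 1.26 and 1.03, Il23r at 0.135 and 0.16 and Stat3 at 84.3 and 86.0. Ccl20 was at 0.173 and 2.098 FPKM and was not tested in the authors' deposited table. The regulatory T cell list had a median of 0.08 at percentile 97.48, where Il10ra rose from 5.08 to 10.3 FPKM and Foxp3 stood at 3.35 and 4.90 without a call, with 1 member called and 2 higher adjusted over the list alone.

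The other lists in Th0 that are given in this paragraph stayed within 0.07 of 0. The medians were -0.02 for the Tfh list, in which Cxcr5 rose from 3.24 to 5.97 FPKM, 0.03 for TGF-β responsive genes, in which Id2 rose from 22.8 to 37.1, and 0.06 for genes responsive to IL-6 and STAT3, none of which was called. The list of T cell activation had a median of -0.04, with Tnfrsf9 (4-1BB) rising from 32.0 to 51.3 FPKM and Tnfsf11 (RANKL) falling from 187.7 to 132.6. That of antigen-experienced cells had 0.06, with Anxa2 rising from 25.8 to 56.5. The death receptor and apoptosis list had 0.05, with the BH3-only gene Pmaip1 rising from 3.41 to 7.28 FPKM. The lists adjusted over the list alone gave 2 higher and 1 lower for Tfh, 2 and 0 for TGF-β, 1 and 0 for IL-6 and STAT3, 3 and 4 for activation, 2 and 0 for antigen-experienced cells and 1 and 1 for apoptosis, from the p-values of the authors' deposited table. Sterol synthesis stood at -0.05 and immediate early and heat shock genes at -0.01, cell cycle genes at 0.00, ribosomal proteins at -0.02 and reference genes at -0.03, with 0 called over all genes and 0 adjusted over the list alone.

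Replication-dependent histone genes, whose mRNAs lack poly(A) tails, had a median of -0.33 over 47 expressed members, at percentile 0. Of these 41 were lower, 9 by at least 1.5-fold, and 0 were called in the authors' deposited table over all genes or adjusted over the list alone. Hist1h2bh stood at 4.66 and 1.34 FPKM and Hist1h2bj at 4.96 and 1.51, and copies of these genes are nearly identical. The 91 expressed neighbours of Fas on chromosome 19 had a median of 0.03, with 1 called, Ide, which fell from 80.9 to 59.6 FPKM and was the 1 adjusted over the list alone.

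Among markers of other cells in the Th0 samples, some that T cells also express were well above 1 FPKM, with Ctss at 63.7 and 60.6 FPKM, Cst3 at 53.3 and 44.0 and Eomes at 15.7 and 15.5. Cd8b1 stood at 9.47 and 10.5 FPKM and Cd8a at 0.561 and 0.913, while Cd19 was at 0.225 and 0.593. The B cell list had 3 expressed members, Fcer2a, Spib and Cd79b, each higher in the Fas-deficient sample, with a median of 0.36 at percentile 95.7 and Cd79b at 1.62 and 2.27 FPKM. The myeloid list had 3, Cst3, Ctss and Cd68, with a median of -0.07 at percentile 18.1, and the CD8, NK and γδ list 2, Cd8b1 and Eomes, with a median of 0.06. The list of genes of the unusual T cells of lpr mice had a median of -0.02 over 10 members. Tnfrsf9 of this list rose, and 3 were higher and 1 lower adjusted over the list alone, from the p-values of the authors' deposited table. No red cell marker was expressed in Th0 or Th17, and no mitochondrially encoded gene was matched. Xist stood at 80.2 and 80.1 FPKM in Th0 and at 73.7 and 78.0 in Th17, while the Y-linked Kdm5d was listed at 0 in all 4 samples.

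By size alone, 75 of 10785 expressed Th0 genes were at least 2-fold higher and 76 at least 2-fold lower in the Fas-deficient sample. Of these 151, 105 were of the kinds counted and not named (predicted genes, pseudogenes, receptor segments, snoRNAs and microRNAs). Of the same 151, 71 were not tested in the authors' deposited table. The median log2 ratio of expressed genes was 0.003 and its robust SD 0.142. The counts at 2-fold depended on the pseudocount, with 148 higher and 122 lower at 0.1.

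In Fas-deficient Th17 cells, the lists of interferon-induced and Th1 genes had higher medians, and the signature Th17 cytokine gene was lower. Il17a, on chromosome 1 from 20720986 to 20724577, fell from 1059.7 FPKM to 709, a log2 ratio of -0.58. Tbx21, on chromosome 11 from 96959321 to 96976645, rose from 2.92 to 9.38 FPKM, a log2 ratio of 1.41. Iigp1 rose from 1.37 to 9.13 FPKM and Irf1, a transcription factor induced by STAT1, from 15.3 to 42.1. The authors' deposited table called 57 of 8869 tested genes, 54 higher and 3 lower in the Fas-deficient sample.

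The Th17 list had a median of -0.19 over 25 expressed members, at percentile 0, and 19 were lower. Il17a was its 1 called member over all genes, and 3 were lower and none higher adjusted over the list alone. The neighbouring gene Il17f stood at 2218 and 1526 FPKM, with q = 0.115 in the authors' deposited table. Rorc stood at 46.8 and 37.9 FPKM, Il21 at 92.6 and 75.1, the transcription factors Ahr and Batf at 54.7 and 43.1 and at 120.3 and 97.0, Tmem176b at 93.4 and 65.9 and the leukotriene receptor Ltb4r1 at 5.59 and 3.20, all uncalled. Other members differed little, with Il23r at 3.19 and 3.25 FPKM, Rora at 28.3 and 28.8, Ccr6 at 115.5 and 119.7, Ccl20 at 67.2 and 67.7 and Stat3 at 154.6 and 169.6. Il2 stood at 534.5 and 460.7 FPKM and Foxp3 at 12.6 and 12.03, both uncalled.

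Interferon-induced genes had a median log2 ratio of 0.45 over 41 expressed members, at percentile 100, and 36 were higher, 14 of them by at least 1.5-fold. Adjusted over the list alone, 20 were higher and none lower, and the authors' deposited table called 10 higher and none lower over all genes. Besides Iigp1 and Irf1 these were Irgm1, which rose from 12.7 to 31.0 FPKM, Gbp5 from 5.96 to 13.9, Gbp4 from 1.61 to 4.42, Gbp2 from 18.6 to 37.3, Igtp from 57.1 to 112.1, the peptide transporter Tap1 from 33.5 to 61.2, the immunoproteasome subunit Psmb9 from 30.0 to 53.1 and Irf8 from 86.4 to 147.6. Stat1 stood at 108.5 FPKM in the wild type and 148.4 in the Fas-deficient sample, with p = 0.0015 and q = 0.164 in the authors' deposited table. Targets of type I interferon went both ways and were uncalled, with Bst2 at 54.7 and 46.4 FPKM, Ifi35 at 23.01 and 21.1, Ifit2 at 3.38 and 3.29 and Isg15 at 0.571 and 0.596, but Dhx58 at 0.569 and 1.547, Isg20 at 0.338 and 1.046 and Ifih1 at 0.971 and 1.635. The list of myeloid markers had a median of 0.44 over 3 expressed members in this sample. Cd68 and Ctss were higher and Cst3 lower, and none was called.

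The Th1 list had a median of 0.52 over 16 expressed members, at percentile 100, and 14 were higher, 7 by at least 1.5-fold. Tbx21 was its 1 called member in the authors' deposited table, and 6 were higher and none lower adjusted over the list alone. Ifng, on chromosome 10 from 117878103 to 117882948, stood at 0.395 and 1.80 FPKM, too low to be tested there. Gzmb stood at 1.72 and 4.24 FPKM, Ccl3 at 13.9 and 23.7, Ccl4 at 31.5 and 53.2 and Il12rb2 at 5.23 and 8.97, all uncalled. Tnf at 139.8 and 137 FPKM and Stat4 at 16.9 and 17.0 differed little.

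Genes of glycolysis and hypoxia had a median of 0.25 over 27 members, at percentile 100, and 26 were higher. The authors' deposited table called 4 higher and none lower, and 8 were higher and none lower adjusted over the list alone. These 4 were Slc2a3, which rose from 20.97 to 51.8 FPKM, Ero1l from 115.9 to 222.3, Ndrg1 from 31.4 to 58.9 and Bnip3 from 75.3 to 119. Aldoc stood at 4.21 and 8.33 FPKM. Genes of amino acid starvation and ER stress had a median of 0.04 at percentile 96.2, with Atf3 at 2.69 and 5.12 FPKM and Ddit4 at 115.7 and 160.2. The authors' deposited table called 0 of them, while 3 were higher when its p-values were adjusted over the list alone.

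Other genes that rose in Fas-deficient Th17 cells were Tnfrsf9 (4-1BB), a costimulatory receptor, from 13.0 to 44.8 FPKM, the glycogen branching enzyme Gbe1 from 4.36 to 13.3, Fscn1, an actin-bundling protein, from 1.30 to 5.10, Slamf7 from 4.86 to 11.5 and the inducible nitric oxide synthase gene Nos2 from 3.05 to 7.60. H2-Q5, a class Ib MHC gene that shares sequence with its neighbours, rose from 14.3 to 36.9 FPKM. Besides Il17a, Mid1 fell from 13.7 to 5.28 FPKM and Lbp, which encodes a lipopolysaccharide-binding protein, from 10.01 to 5.12. Cxcl3 stood at 5.82 and 2.03 FPKM and the histone genes Hist2h2bb and Hist1h3c at 23.5 and 12.4 and at 24.7 and 13.1, uncalled.

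**Figure D2:**
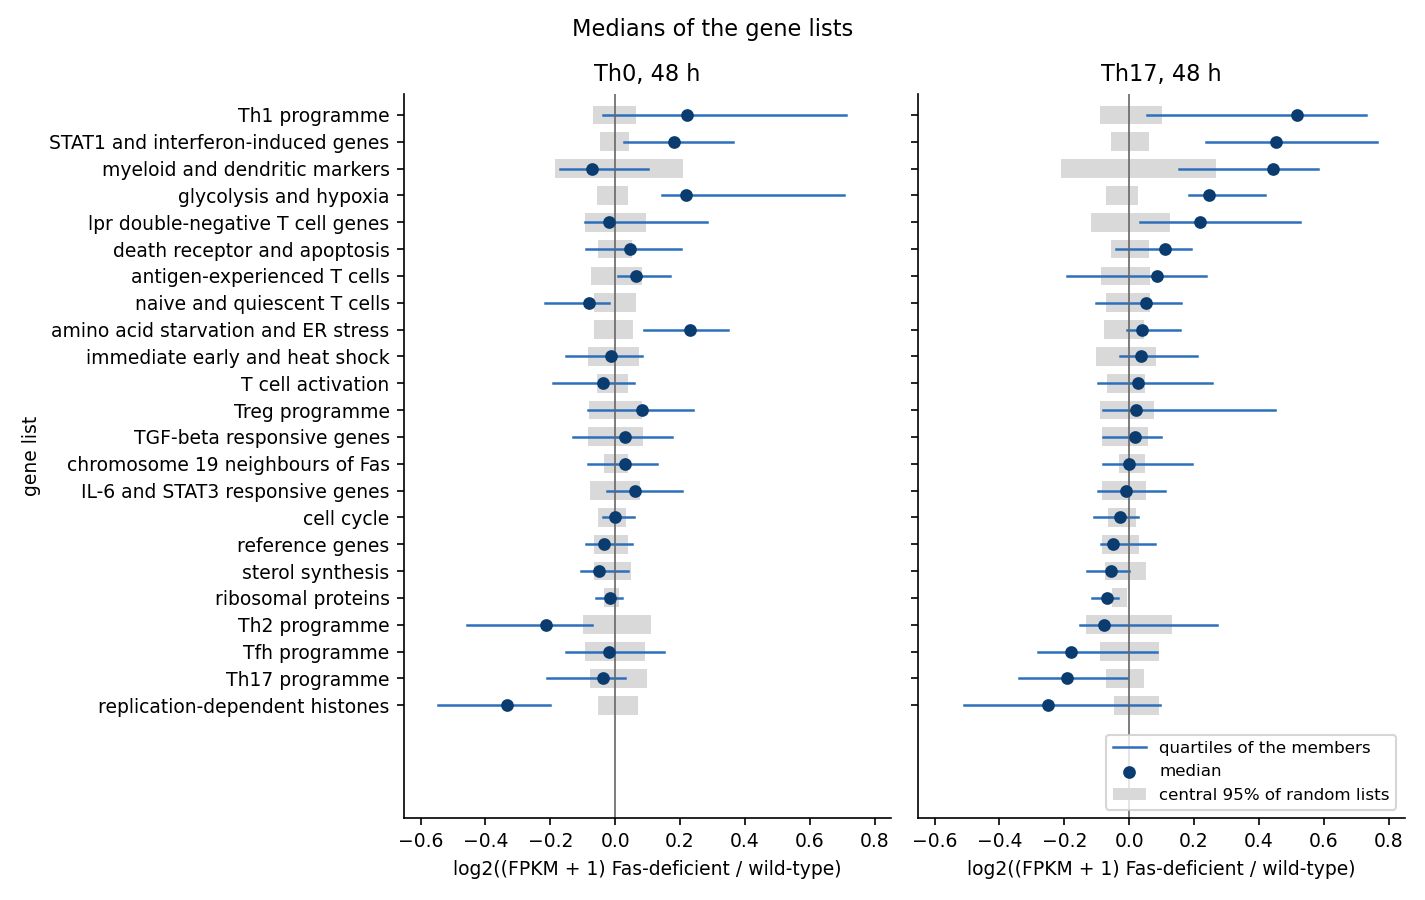
Median log2 ratio of (FPKM + 1), Fas-deficient over wild-type, of 23 gene lists in Th0 (left) and Th17 (right), with the quartiles of the members as lines and the central 95% of 10000 random lists as grey bars. The interferon list stood at 0.18 in Th0 and 0.45 in Th17, and the Th17 list at -0.04 and -0.19.

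Of the other lists in Th17 cells, the Tfh list had a median of -0.18 at percentile 0, with Il6ra at 15.3 and 11.5 FPKM and Cd40lg at 45.6 and 35.8. The authors' deposited table called none of its members, and none passed when its p-values were adjusted over the list alone. The death receptor and apoptosis list had 0.11 at percentile 100, with the cell cycle inhibitor Cdkn1a (p21) rising from 65.3 to 105.1 FPKM as its 1 called member, also the 1 adjusted over the list alone, and Bcl2a1d at 6.08 and 2.99. The list of lpr T cell genes had 0.22 at percentile 99.9, with Tnfrsf9 rising, 1 member higher adjusted over the list alone and the checkpoint receptor Tigit at 3.59 and 6.84 FPKM. Medians were -0.08 for Th2 genes, which turned to 0.10 with no filter, 0.02 for regulatory T cell genes, where Il10ra rose from 1.73 to 4.40 FPKM, -0.01 for genes responsive to IL-6 and STAT3, 0.05 for naive T cell genes, 0.03 for T cell activation and 0.08 for antigen-experienced cells. TGF-β responsive genes stood at 0.02 and turned to -0.004 under upper quartile scaling. Immediate early and heat shock genes stood at 0.04, with Jun rising from 19.9 to 30.7 FPKM. Adjusted over the list alone, 1 was higher for Th2, 3 for regulatory T cell, 1 for activation, 1 for TGF-β and 1 for immediate early genes, and 0 were called either way for the naive, antigen-experienced and IL-6 and STAT3 lists, from the p-values of the authors' deposited table.

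Histone genes had a median of -0.25 over 50 expressed members in Th17, at percentile 0, and 35 were lower, with 0 called in the authors' deposited table. The median was -0.37 over the 23 of at least 5 FPKM, and smaller in size than -0.25 with a pseudocount of 5. Cell cycle genes stood at -0.03, sterol synthesis at -0.06, ribosomal proteins at -0.07 at percentile 0.145, and the 92 expressed neighbours of Fas at -0.0008, again with 0 called, over all genes or adjusted over the list alone. Reference genes had a median of -0.05, with B2m at 932 and 1306 FPKM, 0 called over all genes and 1 higher adjusted over the list alone. Among markers of other cells, Klrd1 stood at 5.07 and 2.78 FPKM, Klre1 at 2.501 and 1.32 and Cd8b1 at 5.79 and 4.49, and the CD8, NK and γδ list had a median of -0.45 over 4 members at percentile 0.13. The myeloid list had a median of 0.44 over 3 members at percentile 99.4, with Ctss, also expressed by T cells, at 19.2 and 26.5 FPKM, Cd68 at 0.797 and 1.97 and 1 higher adjusted over the list alone. Cd79b was the 1 expressed B cell marker, at 1.35 and 0.581 FPKM.

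By size alone, 82 of 10796 expressed Th17 genes were at least 2-fold higher and 60 at least 2-fold lower. Of these 142, 99 were of the kinds counted and not named and 82 were not tested in the authors' deposited table. The median log2 ratio was 0.003 and its robust SD 0.158. With a pseudocount of 0.1 the counts were 173 and 86.

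The difference between the genotypes was then set side by side in both conditions, without a test of how it varied between them. With 1 sample per group, an effect of Fas cannot be told apart from other differences between the mice used. Among 8636 genes tested in both tables, the authors' deposited tables called 70 higher in Th0 and 49 higher in Th17, and 22 were called higher in both, where independent lists would share 0.397. These shared genes included the interferon-induced Gbp2, Gbp5, Igtp and Iigp1, the hypoxia genes Slc2a3, Bnip3, Ero1l and Ndrg1, and Mt1, Mt2, Nos2, Slamf7, Il10ra and Tnfrsf9. In the lower direction 16 and 2 genes were called and 1 was shared, Mid1, where independent lists would share 0.00371. No gene was called in opposite directions. The 2 tables share no sample by their labels, but whether the cultures of a genotype came from the same mice is not known here. The overlap is therefore not a replication of a difference between the genotypes.

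The log2 ratios of the interferon list, as distinct from its levels, were larger in Th17 than in Th0. Their median difference was 0.30, with 32 of 41 members larger. Irf1 stood at 64.6 and 76.3 FPKM in Th0 against 15.3 and 42.1 in Th17, and Tbx21 at 28.7 and 33.6 against 2.92 and 9.38. The Th17 list was lower by a median difference of -0.19, and amino acid stress genes by -0.18. Il2 had log2 ratios of 0.57 in Th0 and -0.21 in Th17, and Ifng of 2.48 and 1.00, but the authors' deposited table, without the pseudocount, gives Ifng log2 fold changes of 2.67 and 2.19. Over the 10366 genes expressed in both, the log2 ratios had a Pearson correlation of 0.0544 and a Spearman correlation of 0.211 across genes, which are not independent replicates, and the Pearson correlation was 0.243 among genes of at least 5 FPKM in every sample. Of the 114 genes called in either condition and tested in both, 98 had the same sign, or 86.0%.

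**Figure D3:**
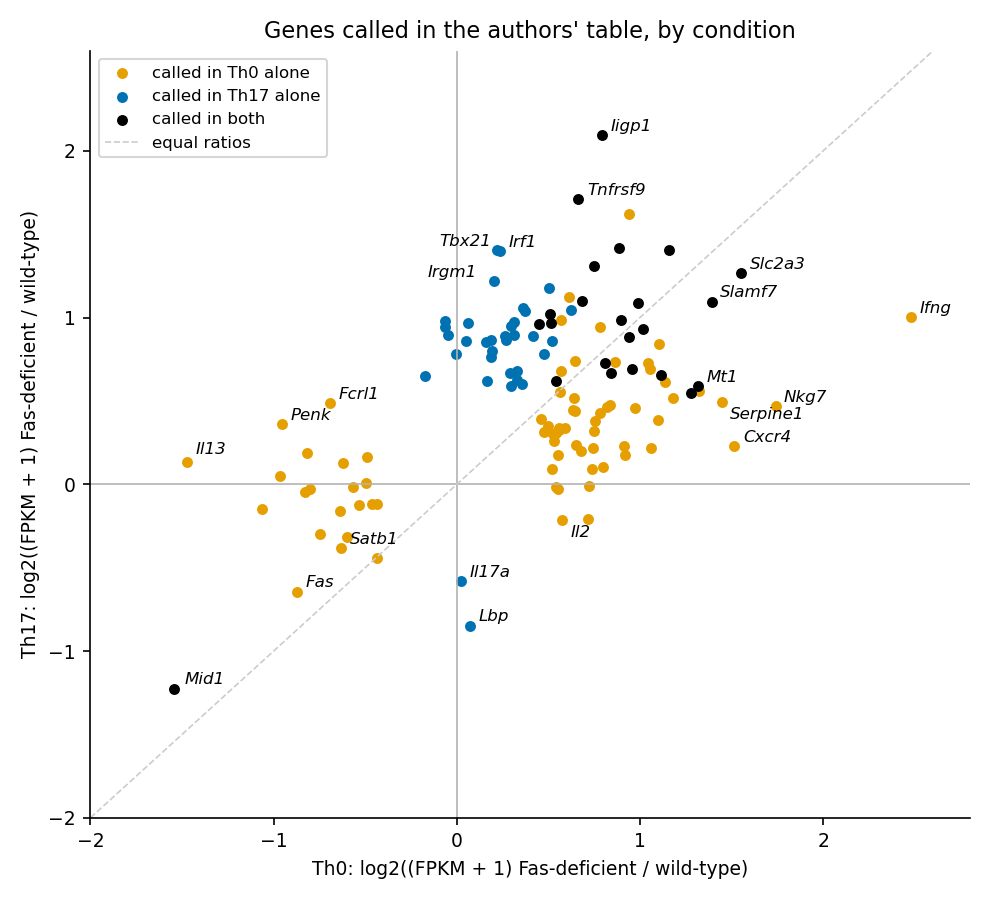
Log2 ratio of (FPKM + 1), Fas-deficient over wild-type, in Th0 (x axis) and Th17 (y axis) of 130 genes called in the authors' deposited tables, coloured by where they were called, with a dashed line of equal ratios. Rnu12, listed at 0 in a sample of each condition, is left out, and Mid1 stands at -1.54 and -1.22.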

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

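No test is reported in this part, and the gene was singled out because its single samples moved in opposite directions in Th0 and Th17, by at least 1.5-fold. The small nuclear RNA gene Rnu12, which encodes the U12 RNA of the minor spliceosome and lies on chromosome 15 from 82980075 to 82980224, was listed at 20.3 FPKM in wild-type and 0 in Fas-deficient Th0 cells, and at 0 in wild-type and 8.06 FPKM in Fas-deficient Th17 cells. The log2 ratio with the pseudocount was higher by 7.59 in Th17 than in Th0, and this difference was not tested. The RNA is short and has no poly(A) tail, and a value of 0 can be a failed estimate in a table without counts.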

How the results depend on the processing

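No test here was chosen after the result was seen, but the choice of list medians to print was. A gene's log2 ratio counted as kept when it moved by at most the robust SD of all ratios, a list median by at most the width of the central 95% of random lists on either side of its middle, a count within 1.5 times and the correlation within 0.05. Of 1101 values of named genes under an alternative, 213 moved and 0 changed sign among called or 1.5-fold genes. Of 335 list medians 35 moved, and 0 of those outside the random range changed sign. Centring and upper quartile scaling moved none of these gene or list values past those limits. A pseudocount of 0.1 put 148 Th0 genes at least 2-fold higher and 122 lower, and 173 Th17 genes higher. A pseudocount of 5 left 46 higher in Th0 and 47 in Th17. Tested rows alone gave 43 higher and 37 lower in Th0 and 39 and 21 in Th17, since fewer genes enter. Calls of the authors' deposited table that were also at least 2-fold numbered 19 higher and 4 lower in Th0 and 17 and 1 in Th17. At a q-value of 0.01 the Th0 calls lower numbered 13, and the Th17 calls 0 higher and 0 lower, as the smallest q of the authors' deposited table there was 0.0111.

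With a pseudocount of 5 the medians were 0.13 for interferon-induced genes, 0.15 for amino acid stress and -0.24 for histones in Th0, and 0.30 for Th1, 0.32 for interferon-induced genes and -0.15 for histones in Th17. With 0.1 they were -0.41 for histones in Th0 and 0.53 for interferon-induced genes in Th17. With no filter they were 0.11 for interferon-induced genes and -0.083 for Th2 in Th0, and 0.36 for Th1, 0.29 for interferon-induced genes and 0.10 for Th2 in Th17. A filter of 5 FPKM gave 0.29 for Th1 in Th0 and -0.37 for histones in Th17. The means of the members were 0.42 for Th1, -0.34 for Th2, 0.44 for glycolysis and hypoxia and 0.30 for amino acid stress in Th0, and 0.52 for interferon-induced genes, 0.077 for Th2, 0.36 for glycolysis and hypoxia and 0.11 for amino acid stress in Th17. The correlation across genes rose to 0.243 among genes of at least 5 FPKM in every sample. The histone difference between Th17 and Th0 turned to -0.015 there. For the medians, the correlation and this difference the cause was not tested. An analysis of both genotypes paired within condition, with 2 pairs, was not run. The depth is unknown, so no interval for counting error can be given.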

Other observations

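The tests in this part were all chosen after the values were seen, as were the genes of its opening paragraphs and the interferon classes, and after a first run the wording of 2 explanations was narrowed, the scaling test was replaced and the rules of 2 other tests were tightened. The genes of glycogen metabolism given here form no fixed list and were not tested as a group. Ppp1r3b, which targets a phosphatase to glycogen, rose from 2.48 to 5.76 FPKM in Th0 and from 10.3 to 17.2 in Th17. Gbe1 rose from 5.13 to 10.3 FPKM in Th0 and from 4.36 to 13.3 in Th17. Gys1, the glycogen synthase, rose from 7.25 to 11.8 FPKM in Th0 and stood at 13.5 and 19.7 in Th17, and Pgm2 rose from 37.7 to 57.4 in Th17 and stood at 31.7 and 39.1 in Th0.

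Class I MHC genes outside the lists are given as values, with no test of the group. H2-Q5 rose from 33.1 to 56.3 FPKM in Th0 and from 14.3 to 36.9 in Th17, and H2-Q8 rose from 13.4 to 26.6 in Th0 and stood at 1.46 and 6.57 in Th17. The classical H2-K1 stood at 429 and 472 FPKM in Th0 and at 296.1 and 381 in Th17, and H2-D1 at 221 and 244 and at 176.8 and 210.0, uncalled. These genes are close in sequence, and shared reads were not separated here. Nnt, in which the C57BL/6J substrain carries a known deletion, rose from 7.38 to 13.1 FPKM in Th0 and stood at 6.77 and 9.12 in Th17. Ide, on chromosome 19 from 37343231 to 37405103, fell in Th0 and stood at 74.4 and 54.5 FPKM in Th17.

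Interferon-induced genes were higher in both Fas-deficient samples, with medians of 0.18 in Th0 and 0.45 in Th17. A scaling difference common to all genes would shift random lists of the same expression alike. The Th17 median of 0.45 lay above the upper end, 0.06, of their central 95%. That is the comparison already given for the list and not a further test. All expressed Th17 genes had a median log2 ratio of 0.003, so a scaling difference common to all genes is argued against in Th17. The test of variants near Fas acting on neighbouring genes was void, since 0 of the 14 members at least 1.5-fold higher in Th17 lay within 10 Mb of Fas but only 2 expressed members lie there at all, so it excludes nothing. A few CD8, NK or γδ T cells that make interferon-γ, which the sort for naive CD4+ cells should remove, cannot be told apart from an effect of Fas loss in the T cells, because a secreted cytokine needs few cells, although their markers had a median of -0.45 over 4 expressed genes in Th17. Myeloid cells were not tested, and their markers went both ways in Th17, with a median of 0.44 over 3 expressed genes, Cd68 at 0.797 and 1.97 FPKM, Ctss at 19.2 and 26.5, Cst3 at 39.5 and 35.9, Csf1r at 0.235 and 0.0922 and Lyz2 at 0 in both samples.

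Interferon-γ rather than type I interferon as the source cannot be told apart here, because the members were put into classes after their values were seen. In Th17 the median log2 ratio was 0.80 over 21 members put in the interferon-γ class and 0.16 over 12 put in the type I class, a difference of 0.64, and in Th0 the difference was 0.24. Ifng stood at 1.80 FPKM in Fas-deficient Th17 and 37.6 in Fas-deficient Th0, from separate tables.

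The list of replication-dependent histones had medians below 0 in both Fas-deficient samples, at -0.33 in Th0 and -0.25 in Th17. In Th0 41 of 47 members were lower and 6 higher, in Th17 35 of 50 were lower and 15 higher, and 0 were called. Fewer cells in S phase, with S phase transcripts falling alike, is argued against in the Th0 samples alone. The 17 S phase genes had medians of 0.0047 in Th0 and -0.029 in Th17. Their bootstrap intervals over genes ran from -0.009 to 0.04 and from -0.11 to 0.006. These lay above levels of -0.17 and -0.12, set between 0 and the histone medians of the same samples after the values were seen. The histone medians had intervals from -0.50 to -0.24 in Th0 and from -0.37 to -0.05 in Th17. The Th17 histone interval overlaps that of the S phase genes, so the question cannot be decided there. The intervals measure the spread among these genes and not an error between samples. Less RNA without poly(A) tails in the Fas-deficient samples cannot be told apart from an effect of genotype, because other such RNAs had a median of -0.33 in Th0, with an interval from -0.55 to -0.16, and of 0.015 in Th17, with one from -0.18 to 0.42. A change in histone transcripts themselves stays open and was not tested.

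The low values bear on how many libraries stand behind each value. In a single library counted in whole reads and scaled to full gene length, single-exon genes would lie at whole multiples of a step in FPKM times length in kb. In wild-type Th17 the smallest step was 0.0769, and 13 genes lay well between 1 and 2 steps, 9 of them within 10% of 0.12. In wild-type Th0 there were 10, in Fas-deficient Th17 3 and in Fas-deficient Th0 0. At least the wild-type values may therefore average more than 1 library. The splitting of shared reads and scaling to a length other than the full one were not tested as other sources.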
